A study of Mus musculus with 8 samples.

How the data were processed

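The data are poly(A)-selected, strand-specific RNA sequencing libraries of CD4+ T cells from the spleen of wild type and Sub1 knockout mice on day 7 of experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis. There were 4 libraries per genotype. Nothing in the labels says that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

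The deposited table gives 1 whole-number count per gene and library, per the file headers, and whether 1 count is a read or a fragment is not stated. The same deposited table gives FPKM (fragments scaled by transcript length and library total) per gene and library, as computed by the authors. Per the submitters' processing notes, cutadapt 1.9, FastQC and HISAT2 2.2.1 were used with the mouse genome build mm10. The program that counted, its treatment of reads that map to several places, the strand setting and the annotation release are not given in the sources used here. Reads shared between ribosomal protein genes and their processed pseudogenes, between Sub1 and its copies, or between overlapping genes can therefore be divided in ways that the table does not show. Of the 31188 genes in the table, 31089 had an identifier in GENCODE M21, and 28336 of these had the same start and end there. Coordinates are those of the deposited table on mm10. A gene name was shared by more than 1 row for 62 names, and such rows were kept apart by identifier.

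The counts summed to between 48.9 M and 57.2 M per library (M, the metric prefix mega). The total implied by FPKM, count and transcript length was larger, and the listed genes held 85.1% to 91.4% of it. No 2 libraries of a group had counts that agreed within sampling noise, since chi-square per degree of freedom was at least 36.0 for the closest pair, so each library was counted as 1 sample.

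Before the data were examined, the design named limma on FPKM as the main test, with edgeR on counts in its place if the table also held counts. It did, so the main test was edgeR 4.0.16 quasi-likelihood with TMM scaling in R 4.3.3, with genotype as the only term, on the 14944 genes with a mean FPKM of at least 0.5 over the 8 libraries. The tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 differences are knockout minus wild type. Their standard errors (SE) were derived from the quasi-likelihood F statistic. Sub1 and Dock2 were also compared with an exact permutation test on log2(FPKM + 1), for which 4 against 4 libraries cannot give a two-sided p below 0.0286.

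The 36 gene lists were fixed before the data were examined and tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01. Beside this stand camera with the correlation estimated per list, fry, and the count of members past the threshold. Members were counted over all genes tested and also adjusted over the list alone. The adjustment over the list alone was made within each list, so it does not correct for testing 36 lists that share members. The rule for named genes, also fixed then, took Sub1, Dock2, up to 12 higher and 12 lower genes of the largest absolute log2 difference among called genes whose 4 knockout values all lay on one side of the wild type values, and up to 4 members of the smallest p per list discussed. Names of the Gm and Rik series, pseudogenes and single antigen receptor segments were left out of the first part of the rule. Lists of intestinal, pancreatic, skeletal muscle, liver and skin transcripts and the test of KEGG and Reactome terms (10 to 500 tested genes each, against the tested genes with a term) were added after the data had been seen.

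The alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, TPM, median-of-ratios and quantile scaling, limma with and without a variance trend or with array weights, DESeq2 1.42.0, a replicate block, leaving out each library in turn, and removal of immunoglobulin, haemoglobin and mitochondrial genes. Library totals without TMM and leaving out 2 libraries with intestinal transcripts or 2 with stromal transcripts were added after the data had been seen. On simulated counts for the 14944 genes of the comparison, edgeR recovered 40% of the 50 genes changed 1.5-fold, 60% of those changed 2-fold, 92% of those changed 3-fold and 96% of those changed 4-fold, and 6.71% of its calls were unchanged genes.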

Results

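The transcriptomes of splenic CD4+ T cells were compared between 4 wild type and 4 Sub1 knockout libraries, prepared on day 7 after the start of EAE. Sub1 encodes a DNA-binding transcriptional coactivator, and Dock2 encodes a guanine nucleotide exchange factor that activates Rac in lymphocytes. The series title names the Sub1 and Dock2 genes together with the migratory capacity of CD4+ T cells. The total count was 53.1 ± 2.84 M (SD, n = 4) per wild type library and 54.0 ± 3.20 M (SD, n = 4) per knockout library, a difference within the spread between libraries (exact permutation p = 0.686, two-sided).

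Sub1 and Dock2 were both lower in each of the 4 knockout libraries than in any wild type library. Sub1 (ENSMUSG00000022205, mm10 chromosome 15, 11981339 to 11996983) was at 28.2 ± 1.58 FPKM (SD, n = 4) in wild type and 9.48 ± 2.30 FPKM (SD, n = 4) in knockout libraries, which is 33.7% of the wild type level. It fell by 1.61 on the log2 scale (SE 0.13, edgeR adjusted p = 0.00144, exact permutation p = 0.0286, the smallest that 4 against 4 libraries can give). Dock2 (ENSMUSG00000020143, mm10 chromosome 11, 34226815 to 34783892) was at 75.3 ± 3.99 FPKM (SD, n = 4) in wild type and 21.1 ± 0.944 FPKM (SD, n = 4) in knockout libraries, which is 28.0% of the wild type level. Dock2 fell by 1.86 on the log2 scale (SE 0.08, edgeR adjusted p = 7.44e-06, exact permutation p = 0.0286). The Sub1 counts that remained were between 1521 and 2983 per knockout library. The table holds 1 value per gene, so it does not show from which exons of Sub1 they came.

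**Figure D1:**
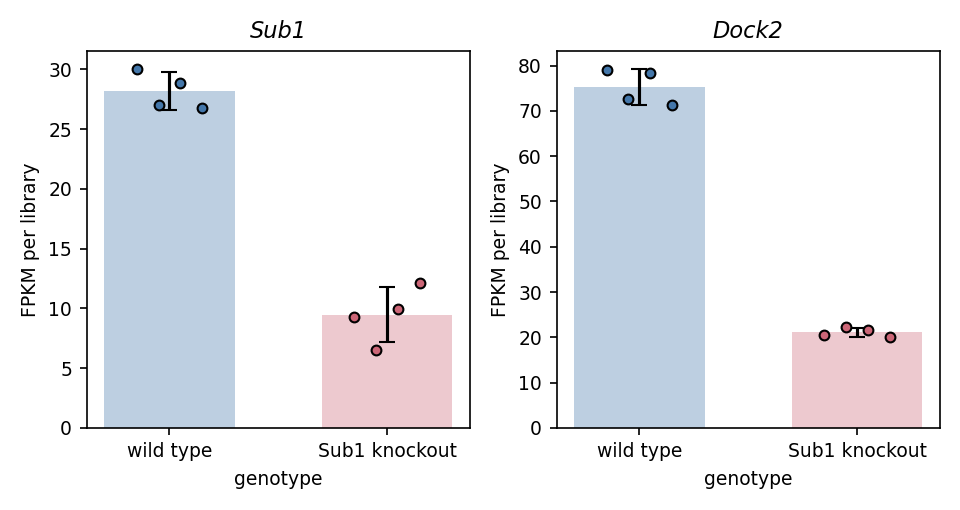
FPKM of Sub1 and Dock2 (vertical axes) in the wild type and Sub1 knockout libraries (horizontal axes), with a point per library, bars at the mean and error bars of 1 SD (n = 4). The knockout libraries lie between 6.56 and 12.1 FPKM for Sub1 and between 20.1 and 22.2 FPKM for Dock2, below all wild type libraries.

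Beyond these genes, more genes were lower than higher in knockout libraries, and cytokine genes were among the largest decreases. Of 14944 genes tested, 250 were called by edgeR, 75 higher and 175 lower, and 54 of them had an absolute log2 difference of at least 1. Il6 fell by 2.90 on the log2 scale (SE 0.57), Il10, an anti-inflammatory cytokine, fell by 1.79 (SE 0.28), Il17a, the signature cytokine of TH17 cells, fell by 1.54 (SE 0.25) and Areg, which encodes the growth factor amphiregulin, fell by 1.56 (SE 0.18). Their edgeR adjusted p-values were 0.0415, 0.0198, 0.0236 and 0.0104. B3galt2, Ermn, Maff, Zbtb10, Gem and Dusp10 completed, together with Sub1 and Dock2, the 12 largest decreases that the naming rule allowed. Their log2 differences lay between -1.98 for B3galt2 and -1.51 for Dusp10. Wild type Il6 was low, at 1.29 ± 0.347 FPKM (SD, n = 4).

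Among the higher genes that the naming rule allowed, Col5a1, which encodes a fibrillar collagen chain, had the largest log2 difference, 1.74 (SE 0.33). It was followed by the natural killer receptor genes Klra8 with 1.67 (SE 0.24) and Ncr1 with 1.54 (SE 0.25). Col5a1 had 569, 690, 325 and 573 counts in knockout replicates 1 to 4 and 95 to 238 in wild type libraries. The stromal collagen gene Col1a1, chosen after its values were seen, had 3830 and 3629 counts in knockout replicates 1 and 2 and 81 to 458 in the other 6 libraries. Without these 2 libraries, a setting also chosen after the data had been seen, the log2 difference of Col5a1 was 1.35 (edgeR adjusted p = 0.134) and 23 genes were called, 6 higher and 17 lower. Tspoap1 rose from 3.75 ± 0.708 FPKM to 11.1 ± 1.57 FPKM (SD, n = 4 each), with an edgeR adjusted p of 0.0028. Abi3bp, Ampd1, Slc35g2, Il9r, Pparg, Gpr15, Ripor3 and Prr33 rose by log2 differences between 1.09 for Abi3bp and 0.90 for Prr33. Il9r encodes a cytokine receptor chain, Pparg a nuclear receptor and Gpr15 a homing receptor of T cells. Col5a1, Klra8, Abi3bp, Slc35g2 and Ripor3 were at less than 1 FPKM in wild type libraries.

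The number of called genes depended on single libraries and on the model. It was 85, 80, 100 and 88 without wild type replicates 1, 2, 3 and 4 and 26, 215, 108 and 30 without knockout replicates 1, 2, 3 and 4, while DESeq2 called 859. The share of higher genes among the calls was 30.0% with TMM scaling, 47.8% with library totals in its place, a setting chosen after the data had been seen, 56.1% with limma on TPM and 45.4% with limma and array weights.

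Genes of T cell activation and the early response were lower in knockout libraries as a group. Of 39 members tested, 38 had a lower value, 10 fell and none rose, and 28 were lower adjusted over the list alone. Junb, a subunit of the AP-1 transcription factor, was at 680 ± 94.4 FPKM in wild type and 364 ± 29.8 FPKM in knockout libraries (SD, n = 4 each) and fell by 0.93 on the log2 scale (SE 0.11, edgeR adjusted p = 0.011). Nr4a2, an orphan nuclear receptor gene, fell by 1.36 (SE 0.18), the MAP kinase phosphatase gene Dusp5 by 1.49 (SE 0.20) and Tnfaip3, an inhibitor of NF-kappaB signalling, by 1.38 (SE 0.20). The list median was -0.41 (camera adjusted p = 9.85e-37 with the preset correlation, adjusted p = 0.0756 with an estimated correlation). Wild type replicate 1 had the highest mean of this list, and without it the median was -0.35.

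Genes of cytosolic ribosomal proteins were lower by a smaller amount but nearly uniformly. All 76 members tested had a lower value under the main scaling, 28 fell, and 71 were lower adjusted over the list alone. Rpl39 fell by 0.40 on the log2 scale (SE 0.05), Rps16 by 0.43 (SE 0.06), Rpl36 by 0.34 (SE 0.05) and Rpl23a by 0.36 (SE 0.05). The list median was -0.31 (camera adjusted p = 1.58e-55 with the preset correlation, adjusted p = 0.0714 with an estimated correlation), and it was -0.15 after quantile normalization. An rRNA row (ENSMUSG00000106106, mm10 chromosome 17, 39846353 to 39848201), chosen after its values were seen, was higher in knockout libraries. It was at 328 ± 70.1 FPKM in wild type and 564 ± 62.3 FPKM in knockout libraries (SD, n = 4 each, edgeR adjusted p = 0.0362). Another rRNA row, ENSMUSG00000118642, rose by 0.90 on the log2 scale (SE 0.14, edgeR adjusted p = 0.0198). The libraries were poly(A)-selected, so these rows need not reflect the rRNA level of the cells.

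**Figure D2:**
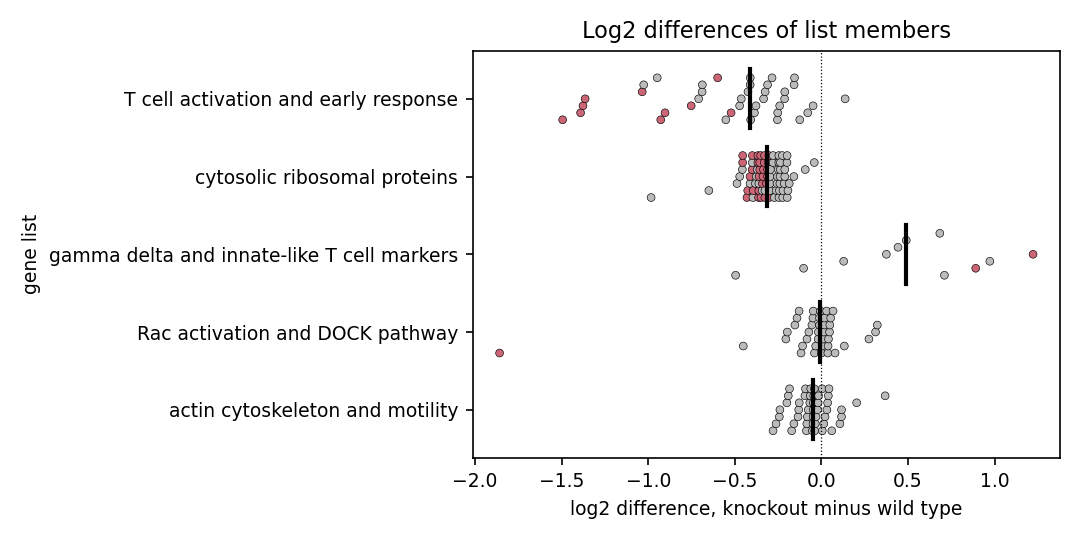
Log2 differences, knockout minus wild type (horizontal axis), of the members of 5 gene lists (vertical axis), with a point per gene, red where the edgeR adjusted p is under 0.05, and a black line at the list median. The medians are -0.41 for the early response and -0.31 for ribosomal proteins, while Dock2 at -1.86 stands apart from the other Rac and DOCK genes, whose list median is -0.01.

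In each of 5 lists of T helper, regulatory and effector T cell states more called members fell than rose. The same held over all genes tested, where 175 of the 250 called genes were lower. The lists share members, such as Il10 and Ccr8 of the TH2 and regulatory lists. The follicular helper list had no called member, and in the naive and central memory list 1 rose and none fell. In the TH1 list, 3 of 24 members fell and 9 were lower adjusted over the list alone. These 3 were Ifng, the signature TH1 cytokine, by 1.14 on the log2 scale (SE 0.23), the interferon gamma receptor gene Ifngr1 by 0.47 (SE 0.06) and Hopx by 0.55 (SE 0.09), while Fasl had a log2 difference of -0.72 (edgeR adjusted p = 0.0572). The TH1 median was -0.17 (camera adjusted p = 1.68e-06 with the preset correlation, adjusted p = 0.105 with an estimated correlation). In the TH17 list, 3 of 22 members fell. Beside Il17a, the transcription factor gene Bhlhe40 fell by 1.03 (SE 0.15) and Nfkbiz fell by 0.77 (SE 0.13), and the chemokine receptor gene Ccr6 rose by 0.70 (SE 0.12). Adjusted over the list alone, 5 were lower and 2 higher, and the median was -0.13 (camera adjusted p = 0.00118 with the preset correlation, adjusted p = 0.23 with an estimated correlation).

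In the TH2 list, 4 of 12 members fell and 2 rose, the same numbers as adjusted over the list alone. Areg, Il10, Ccr8 and Nfil3 fell, the last by 1.25 on the log2 scale (SE 0.16), and Ccr4 and Pparg rose. The median of -0.07 (camera adjusted p = 0.0202 with the preset correlation, adjusted p = 0.235 with an estimated correlation) turned positive under 4 alternatives. In the regulatory T cell list, 4 of 29 members fell and 1 rose, against 14 and 1 adjusted over the list alone. Dusp4 fell by 1.46 (SE 0.21), beside Il10, Ccr8 and Tnfrsf9, and Gpr15 rose by 0.92 (SE 0.15). The regulatory T cell median was -0.28 (camera adjusted p = 1.95e-11 with the preset correlation, adjusted p = 0.12 with an estimated correlation). In the effector and memory list, Cxcr6 and Id2 fell, the second by 0.43 (SE 0.08), and 7 of 27 members were lower adjusted over the list alone. Klrg1 had a log2 difference of -0.90 (edgeR adjusted p = 0.053) and Il2rb of -0.28 (edgeR adjusted p = 0.092). The median of this list was -0.17 (camera adjusted p = 2.58e-08 with the preset correlation, adjusted p = 0.0756 with an estimated correlation).

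For migration, the receptor genes moved in both directions, and Dock2 was the only called gene of the Rac, actin and adhesion lists in the main test. Of 30 chemokine and egress receptor genes and their regulators, 5 fell and 2 rose, and 8 were lower and 2 higher adjusted over the list alone. Cxcr6 fell by 0.93 on the log2 scale (SE 0.08, edgeR adjusted p = 0.00154), Ccr8 by 0.81 (SE 0.13) and P2ry10, a receptor gene for lysophospholipids, by 1.00 (SE 0.17), while Ccr4 rose by 0.69 (SE 0.11). The median of the chemokine receptor list was -0.10 (camera adjusted p = 0.00106 with the preset correlation, adjusted p = 0.23 with an estimated correlation).

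Of 40 genes of Rac activation and the DOCK pathway, 1 fell and none rose, and 2 were lower adjusted over the list alone. Apart from Dock2, the members of the smallest p were Arhgap15, with a log2 difference of -0.45 (edgeR adjusted p = 0.0562), Vav2 with 0.27 and Rhoh with -0.15. The list median was -0.01 (camera adjusted p = 0.0232 with the preset correlation, adjusted p = 0.572 with an estimated correlation) and turned positive under 9 alternatives. None of 48 actin cytoskeleton genes was called, and 5 were lower adjusted over the list alone, among them Capg with -0.28, Cotl1 with -0.24, Myl6 with -0.24 and Coro1a with -0.26. The actin list had a median of -0.05 (camera adjusted p = 0.0182 with the preset correlation, adjusted p = 0.579 with an estimated correlation), which turned positive on TPM and after quantile normalization. None of 36 integrin, selectin and adhesion genes was called, with a median of -0.01 (camera adjusted p = 0.388); adjusted over the list alone 2 were higher, Itga2 and Itgb3, and 3 were lower, Crtam and Itgb1 among them. In the T cell receptor signalling list, Bcl10, an adaptor of NF-kappaB activation, fell by 0.57 (SE 0.07) as the only 1 of 48 members called, also adjusted over the list alone, and Cd28 had a log2 difference of -0.58 (edgeR adjusted p = 0.0997). The median of that list was -0.06 (camera adjusted p = 0.0549).

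Among the stress and metabolic lists, 4 of 28 genes of the unfolded protein response and heat shock fell, Dnajb9 by 0.76 on the log2 scale (SE 0.13), Atf4 by 0.37 (SE 0.07), Bag3 by 0.48 (SE 0.09) and Ddit3 by 0.56 (SE 0.11), and 7 were lower adjusted over the list alone. The median of -0.06 (camera adjusted p = 9.02e-04 with the preset correlation, adjusted p = 0.469 with an estimated correlation) turned positive under 3 alternatives. Pim1 and Birc2 fell in the apoptosis and survival list (median -0.12, camera adjusted p = 2.69e-04, adjusted p = 0.0714 with an estimated correlation), and 7 of its 33 members were lower adjusted over the list alone. Slc2a3, a glucose transporter gene, fell in the glycolysis list (median -0.16, camera adjusted p = 5.98e-04, adjusted p = 0.23 with an estimated correlation), where 3 of 26 were lower adjusted over the list alone. None of 73 nuclear-encoded genes of oxidative phosphorylation was called, also adjusted over the list alone (median -0.10, camera adjusted p = 3.13e-04, adjusted p = 0.667 with an estimated correlation). Nr4a2 and Il10 fell in the list of inhibitory receptors and exhaustion (median -0.14, camera adjusted p = 0.0012, adjusted p = 0.241 with an estimated correlation), where 5 of 19 were lower and 1 higher adjusted over the list alone.

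The lists of S phase, G2 and mitosis, interferon response, sterol synthesis, general transcription machinery, mitochondrially encoded mRNAs and follicular helper T cells had no called member, and their camera adjusted p-values lay between 0.123 and 0.846. Adjusted over the list alone, 1 sterol synthesis gene was lower, and 3 follicular helper genes were lower and 1 higher. Plk2 fell in the list of p53 targets and DNA damage (6 lower and 2 higher of 35 adjusted over the list alone, camera adjusted p = 0.123), and Id3 rose in the list of naive and central memory T cells (1 of 23 higher adjusted over the list alone, camera adjusted p = 0.388).

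Markers of other cell types were on balance higher in knockout libraries for several lists, with few called genes. Among 11 markers of gamma delta and innate-like T cells, 5830411N06Rik rose by 1.22 on the log2 scale (SE 0.12, edgeR adjusted p = 0.00303) and Trdc, the constant gene of the T cell receptor delta chain, by 0.89 (SE 0.15, edgeR adjusted p = 0.0236). Adjusted over the list alone, 7 were higher and 1 lower, and the median was 0.49 (camera adjusted p = 4.68e-07 with the preset correlation, adjusted p = 0.0714 with an estimated correlation). Klra8 and Ncr1 were the 2 called members among 13 natural killer cell markers, 3 of which were higher adjusted over the list alone (median 0.29, camera adjusted p = 1.88e-04, adjusted p = 0.241 with an estimated correlation).

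No marker of B cells, monocytes and macrophages, or erythroid cells and platelets was called, also adjusted over the list alone, although their medians were 0.46, 0.41 and 0.87. Their camera adjusted p-values were 6.72e-05, 0.00233 and 2.69e-04 with the preset correlation and, in the same order, adjusted p = 0.469, 0.667 and 0.579 with an estimated correlation. The neutrophil median was -0.14 (camera adjusted p = 0.674), the stromal and endothelial median 0.70 (camera adjusted p = 0.0501; -0.07 without knockout replicates 1 and 2), the dendritic cell median -0.02 (camera adjusted p = 0.824), the plasma cell median -0.09 (camera adjusted p = 0.117) and the CD8 T cell median 0.02 (camera adjusted p = 0.683), with no called member in any of them and, adjusted over the list alone, 1 lower plasma cell marker and 1 lower CD8 T cell marker. Some of these markers were well expressed. The neutrophil gene Mpo was at 271 ± 69.2 FPKM in wild type and 215 ± 95.6 FPKM in knockout libraries (SD, n = 4 each). Hmox1 of the monocyte and macrophage list was at 101 ± 48.4 and 202 ± 92.8 FPKM, while Ms4a7 of that list was at only 0.408 and 0.762 FPKM. Differences between these libraries therefore need not be those of CD4+ T cells alone. With the preset correlation 20 of the 36 lists had a camera adjusted p under 0.05, with an estimated correlation 0 did, and with fry 12 did. Of the 35 splits of the 8 libraries into 4 and 4, the real one included, 5 gave 20 or more lists with the preset correlation.

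Genes of other tissues, in lists written after the data had been seen, stood out in single libraries of both genotypes. Intestinal epithelial genes summed to 314 CPM (counts scaled to the library total) in wild type replicate 1 and 163 CPM in knockout replicate 4, and to at most 18.4 CPM in the other 6 libraries. Without these 2 libraries 31 genes were called, 6 higher and 25 lower.

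**Figure D3:**
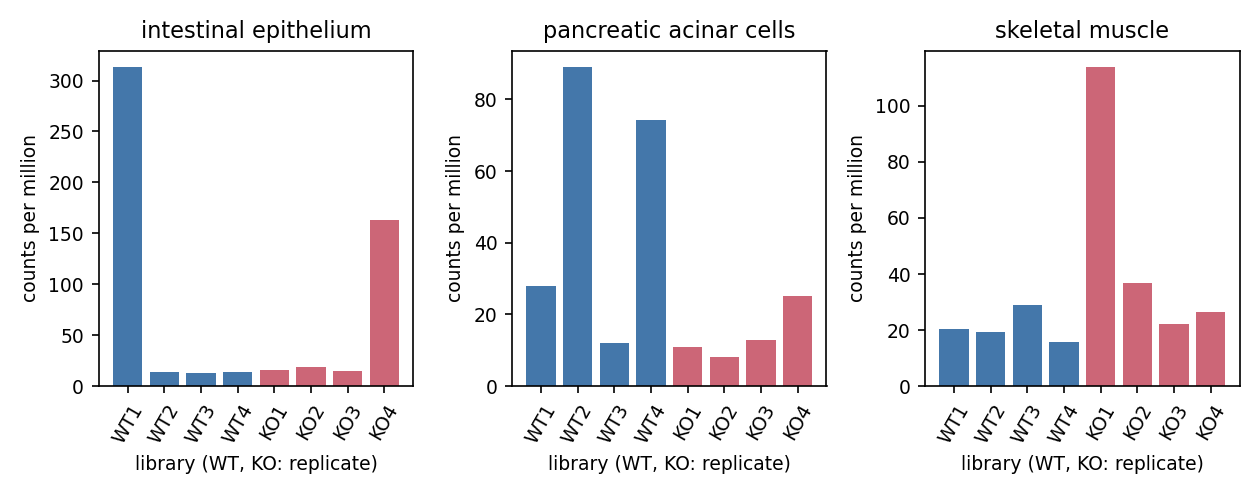
Summed CPM (vertical axes) of intestinal, pancreatic acinar and skeletal muscle genes in each library (horizontal axes; blue wild type, red Sub1 knockout). Intestinal genes stand out in wild type replicate 1 (314) and knockout replicate 4 (163).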

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

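For 9 of 244 groups of 4 libraries examined, 1 library lay far from the other 3, where chance gives about 12.2, so their number is no more than chance gives. Of the 9, 6 were in wild type replicate 1. There Dusp10 was at 68.7 FPKM against 31.3 in the nearest wild type library, Junb at 820.5 against 649, Cd28 at 106.5 against 75.9 and Ripor3 at 0.517 against 0.371. The mean log2 CPM of the early response list was 7.50 in that library against 7.24, and the listed genes held 91.1% of the total implied by FPKM against 89.2%. The remaining 3 were the total count of wild type replicate 2, at 48.9 M against 53.9 M, Rpl39 in knockout replicate 2, at 40.1 FPKM against 45.7, and Itgb3 in knockout replicate 1, at 19.9 FPKM against 17.0.

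The number of called genes, 250, was reached by 1 of the 35 splits of the 8 libraries into 4 and 4, which is the real one. The highest of the other splits gave 3. This argues against chance for the number, but 1 of 35 is the smallest share these splits can give. Every other split mixes the genotypes, which widens the spread within its groups, so the gap from 3 to 250 does not measure strength. For the number of lists with a camera adjusted p under 0.05 at the preset correlation chance cannot be excluded, since 5 of the 35 splits gave as many as the real 20, with 22 in the highest of the others.

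For the lower early response genes, without each library in turn the list median stayed at -0.35 or lower, which argues against a single library as the source. Of the 35 splits, 1, the real one, gave a median as far from 0 as 0.41, with 0.35 in the highest of the others. That is the smallest share these splits can give, and the camera adjusted p with an estimated correlation was 0.0756. Chance is argued against, but not excluded, and only for this list taken alone. It was picked among 36 lists after its values were seen, which the splits do not adjust for. Fewer cells of another type would lower the markers of that type. The B cell and the monocyte and macrophage medians were 0.46 and 0.41, so their markers were not lower as a set. The neutrophil median, the lowest of the 3, was -0.14, above the list by 2.64 standard errors. That standard error treats genes as independent, although the estimated correlation of the neutrophil list was 0.79, so for neutrophils the gap does not decide. Cells of other types were not covered by these 3 lists. For a stress response to cell isolation with heat shock, the 6 heat shock genes, 3 higher and 3 lower, had a median of 0.095. This lay above the list median by 0.51, more than their SD of 0.40. Bag3, the only called gene of the 6, fell by 0.48 (edgeR adjusted p = 0.0377), while Hspa1a and Hspa1b rose with SEs of 0.38 and 0.41. The 6 genes did not move as a set, so they do not decide on such a response. An isolation response without heat shock and a biological difference of the genotypes also stay open and were not tested.

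The lower ribosomal protein genes were weighed against 2 technical explanations. After the trend with transcript length was subtracted the list median was -0.27. This lay below the 2.5th percentile of 10000 random lists of the same size, -0.05, and below that of random lists matched on expression, -0.07. Those percentiles come from genes drawn at random, so they do not allow for the estimated correlation of 0.31 within this list. Relative to all tested genes the median was -0.15 or lower under each of 6 scalings, so neither length nor scaling accounts for the whole difference. Of the 35 splits, 1, the real one, gave a median as far from 0 as 0.31, with 0.21 in the highest of the others. This is the smallest share the splits can give. It argues against chance, without excluding it, only for this list taken alone, since the list was also picked among the 36. RNA quality and reads shared with pseudogenes were not tested and stay open, beside the genotype.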

How the results depend on the processing

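Library totals without TMM and the omission of wild type replicate 1 and knockout replicate 4 (intestinal transcripts) or of knockout replicates 1 and 2 (stromal transcripts) were chosen after the data had been seen. Sub1 and Dock2 kept their direction and an adjusted p under 0.05 under each alternative run, with log2 differences of -1.72 to -1.42 for Sub1 and -1.94 to -1.74 for Dock2.

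The count of 250 called genes (75 higher, 175 lower) was 105 (28 and 77) without a filter, 148 (46 and 102) after quantile normalization, 162 (98 lower) with limma without a trend, 859 (331 and 528) with DESeq2, and 54 (13 and 41) at an absolute log2 difference of at least 1. Limma on TPM gave 119 higher and 93 lower genes, array weights 124 higher and library totals without TMM 128 higher. Without the 2 libraries that held intestinal transcripts it was 31 (6 and 25), of which 30 were among the 250, and without the 2 that held stromal transcripts 23 (6 and 17), of which 15 were. Leaving out 1 library gave 26 to 215 called genes, 6 to 46 higher and 19 to 169 lower. The fits with fewer libraries or more genes tested lose power by construction, and for the other settings the cause was not tested. The limma settings on FPKM differ from the main test in the model as well. All 250 genes, or those still tested, had their main direction in each alternative fit. In 249 of them all 4 knockout values lay on one side of the wild type values. A reversal was therefore hardly possible, and the kept direction says little about robustness.

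Replicate numbers are shared between the genotypes. Deviations of equal numbers correlated at -0.21, 0.10, 0.12 and -0.15, and only 1 of 4 wild type libraries correlated best with its own number. Wild type replicate 1 correlated best with knockout replicate 4 (0.28), the other library with intestinal transcripts. These values give no sign of a pairing by number. They cannot exclude one, and nothing in the labels settles it. With the replicate number as a block 14 genes were called, 4 higher and 10 lower, of which 12 were among the 250.

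Among gene lists, 20 had an adjusted p under 0.05, against 0 with an estimated correlation and 12 with fry, and 14 to 24 under the other alternatives. DESeq2 gives no camera test, so this was not run. Medians near 0 changed sign, and the cause was not tested. The Rac and DOCK median was 0.0090 at a mean FPKM of at least 5, 0.0041 without knockout replicate 4, 0.039 with library totals, positive with limma on log2(FPKM + 1) with or without a trend and with a pseudocount of 0.1 (0.019, 0.019 and 0.020), 0.082 on TPM, 0.058 after quantile normalization and 0.016 with array weights. The actin median was 0.043 on TPM and 0.055 after quantile normalization. The TH2 median was 0.0082 without knockout replicate 3, 0.020 without the 2 libraries with intestinal transcripts, 0.022 on TPM and 0.014 over members in 1 list only. The unfolded protein response median was 0.061 without knockout replicate 2, 0.0045 on TPM and 0.021 with array weights. Leaving out 1 library gave medians of -0.028 to 0.0041 for Rac and DOCK, -0.17 to 0.0082 for TH2 and -0.18 to 0.061 for the unfolded protein response. For single named genes, 1327 values kept their side of the threshold, 485 lost and 35 gained it, and none reversed. These genes had been picked for separated groups or a small p, which made a reversal unlikely. Simulation at this depth recovered 40% of genes changed 1.5-fold, so smaller differences can be missed.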

Other observations

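The lists of other tissues and the tests of annotated terms were chosen after the data had been seen. The 175 lower genes were enriched for the KEGG term Ribosome (hypergeometric test, adjusted p = 1.60e-23 over 295 terms). It held 30 lower genes among its 130 tested genes, against 2.44 expected. The ribosomal protein list had already shown 28 lower genes, so the term is no separate support. The hypergeometric test treats genes as independent, although the estimated correlation of that list was 0.31. The KEGG term of the second smallest p, cytokine-cytokine receptor interaction, held 9 lower genes against 2.59 expected (adjusted p = 0.149). No KEGG or Reactome term had an adjusted p under 0.05 among the higher genes.

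Transcripts of other tissues stood in single libraries of both genotypes. The 16 intestinal epithelial genes summed to 314 CPM (counts scaled to the library total) in wild type replicate 1 and 163 in knockout replicate 4, against 12.6 to 18.4 in the other 6 libraries. Lypd8 had 3721 counts in wild type replicate 1, 2399 in knockout replicate 4 and at most 18 elsewhere. The 19 pancreatic acinar genes reached 89.1 and 74.2 CPM in wild type replicates 2 and 4, and Pnlip had 320 and 226 counts there. The 15 skeletal muscle genes reached 114 CPM in knockout replicate 1, where Acta1 had 1033 counts. The stromal collagen gene Col3a1 had 3654 and 3905 counts in knockout replicates 1 and 2 and at most 529 elsewhere. The 5 skin genes were highest in wild type replicate 4, at 8.98 CPM. The liver list, 4 genes of which Trf gave nearly all counts, ranged from 36.5 to 171 CPM.

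The lower Dock2 level was weighed against 3 technical explanations. Scaling or depth is argued against, since 6 scalings moved the log2 difference by at most 0.12. A difference across the genome between C57BL/6J and a substrain with intact Nnt is argued against as well. Nnt, which is deleted in part in C57BL/6J mice, differed by -0.10 (SE 0.31), where more than 1 was predicted. Wdfy1 and Entpd4 were not called. Nnt counts spread within the groups, from 1256 to 2526 in wild type and 1534 to 2537 in knockout libraries. Substrains that all carry intact Nnt would leave it level, so a difference between them was not tested. A different haplotype around Dock2 cannot be told apart from an effect of Sub1, because 1 of 34 tested genes within 5 Mb, Il9r, was called (one-sided Fisher's exact p = 0.437), too few to decide. As a hypothesis, a segment that carries a changed Dock2 copy on an otherwise matched background, as has been described for some C57BL/6 colonies, may lower Dock2 without an effect of Sub1, and the genotype at Dock2 was not analysed here.

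Of 28 tested genes within 5 Mb of Sub1, 0 were called by edgeR (one-sided Fisher's exact p = 1), which allows a share of up to 12.3% (exact 95% binomial bound), so this test does not decide whether a flanking segment was carried with the targeted allele.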
